A study of Homo sapiens with 16 samples.

How the data were processed

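RNA from 16 cultures was measured on 16 custom Agilent arrays with 1 dye (Cy3), and each array carried 62976 spots. Of these, 1439 were control spots and the others held 57176 distinct probes, 23042 of them added for this array design. The probe signals are linear spot intensity values per the file headers, with the background subtracted and spatial trends removed within each array. Feature Extraction 10.5.1.1 is named per the file headers, while the submitters' processing notes name version 9.1, and which applies is not settled here. No scaling between arrays is recorded for these intensity columns. A table for the whole series holds the authors' deposited log2 values for 46729 of the probes. Against the scanner signal its slope lay between 0.996 and 0.998 with a different offset for each array, so its scale is log2. Its column medians ran from 5.797 to 6.138. How the arrays were scaled in that table is not given in the sources used here. No genes were centred in it, and its direction is that of the signal.

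The main values were log2 of the processed signal minus the 75th percentile of each array. Control spots and spots with an outlier flag were left out, and no spot was saturated. Spots of a probe were averaged. A probe was kept where it was well above background on at least 4 of the 16 arrays, and each gene was represented by its probe with the highest mean over all arrays. This left 31009 genes or unnamed transcripts. Symbols came from RefSeq accessions in the files, matched without version to the RefSeq gene table of GRCh38.p14. In this way 25742 of the 57176 probes (45%) matched a symbol, giving 19726 genes. The files use hg19, so no coordinates are printed and the table served only for names, gene classes and neighbours. Custom probes carry transcript IDs, 12425 with an Ensembl transcript ID and 10565 with a TCONS ID, which have no symbol in the tables used here.

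Arrays were grouped by treatment and time from the labels, 4 in each of the groups DMSO 12 h, GSI 12 h, DMSO 48 h and GSI 48 h. Each cell line gave 1 array per group. The labels give no repeat cultures within a line, so the cell lines are the replicates (n = 4). p-values of the GSI effects at 12 h and 48 h measure the spread between these lines pooled over both times. Because the same line stands in every group, GSI and DMSO arrays of a line were paired within each time. Deviations from the group means correlated at 0.809 or more within a line and at -0.011 or less between lines, and 16 of 16 arrays correlated best with their own line. Subtracting the mean of 4 lines itself pushes correlations between lines below 0, so those values add little. The check shows that arrays share a cell line, while the pairing within a time was taken from the labels. The GSI effects at 12 h and 48 h were fitted together over the 16 arrays with a term for each of the 8 pairs, using lmFit and eBayes in limma 3.58.1 (R 4.3.3, with data.table at version 1.17.8). Residual degrees of freedom were 6 and prior degrees of freedom 2.25. Each gene thus has the same standard error at 12 h and 48 h, and the fit counts both times of a line as independent. The 48 h p-values therefore do not rest on the spread at 48 h alone. For the averaged effect, the difference between times and the change in DMSO cultures, 1 value per cell line was formed and its mean tested in limma. A moderated F test in limma compared cell lines. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors are standard errors of the limma coefficient unless named otherwise.

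Before the data were examined, 19 gene lists, the tests of the comparisons described here and all but 1 of the alternatives were fixed. Tests of gene families, spike-ins and slide position were chosen after seeing results. Lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, all from limma. camera compares a list with the other genes, while fry asks whether the genes of a list move one way on balance. Shares of lncRNAs and protein-coding genes past the threshold were compared with Fisher's exact test, with 8 further tests within classes of mean level. Named genes followed a rule fixed with the tests. At 12 h and 48 h these are the 10 largest rises and 10 largest falls, and the 5 lncRNAs with the largest rise and fall, among genes past the threshold that moved one way in all 4 lines. The brighter group had to be well above background on at least 3 of 4 arrays. Where none passed, the 5 genes per direction with the smallest unadjusted p that moved one way in all 4 lines stand in. For other contrasts the 5 largest per direction were taken, for cell lines the 10 genes with the smallest p, and for lists every NOTCH1 target and 4 members of each other list. A gene that was not well above background on any array of a group has only a bound there. The bound sets the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

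The scripts were tested on simulated data over 30904 genes with planted changes. At 48 h the fit recovered 3% of planted log2 changes of 0.5, 62.7% of those of 1 and 92.4% of those of 2, and at 12 h 4.5%, 64.2% and 95.5%. For the averaged effect recovery was 6%, 67.2% and 97%, for the change in DMSO cultures 0%, 32.8% and 90.9%, and for the difference between times 0%, 0% and 60.6%. For the F test between cell lines it was 0% at each size. A planted list of 25 genes shifted by 0.4 had an adjusted p of 5.87e-24 with camera's preset correlation, 0.00573 with the estimated one and 0.00163 with fry, while 0 of 18 other lists passed in each. The simulated genes varied independently, so these values cannot show how often the preset correlation of 0.01 calls lists of genes that vary together. In the real data the estimated correlation was 0.402 for ribosome biogenesis, 0.318 for mitosis and 0.83 for cholesterol genes.

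The alternatives were scaling to the array median, quantile normalization, normexp background correction with an offset of 50 followed by the 75th percentile or quantiles, the authors' table, no filter on dim probes, a filter on all 16 arrays, each probe alone, the mean of a gene's probes, and eBayes with an intensity trend and robust settings. Further ones were leaving out each cell line, no pairing, the cell line as a block over both times, and only the 8 arrays of a time. normexp was to use mean spot signals. The median spot signal took their place, since it is the column held by the files used here. Scaling to spike-in probes without TALL-1 was added after the data were seen. Slide 1 held HPB-ALL and DND-41, slide 2 TALL-1 and slide 3, read on another scan day, ALL-SIL. Each slide held all 4 groups, so the pair terms already remove slide and scan day. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision. No sample was left out of the main comparisons. A few genes that the naming rule selects are not reported here, and they remain in all counts and list tests.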

Results

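Transcript levels were measured in 4 human cell lines from T-cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T cells often driven by active NOTCH1. The lines were ALL-SIL, DND-41, HPB-ALL and TALL-1. Each was cultured with 1 µM Compound E, a gamma-secretase inhibitor (GSI) that blocks the cleavage step by which NOTCH receptors become active, or with the solvent DMSO. RNA was taken after 12 h and after 48 h, which gave 4 groups of 4 arrays. Medium held 10% serum, or 20% for ALL-SIL. The array combines probes for known genes with custom probes for long non-coding RNAs (lncRNAs), and the series title names lncRNA signatures of GSI treatment as its aim. Between 42.2% and 60.2% of probes were well above background on an array, and the 75th percentile of the signal ran from 396.1 to 910.6. The GSI and DMSO arrays of a pair correlated at 0.9839 or more across probes. Values below are log2 fold changes with the standard error of the limma fit over 4 cell lines, and adjusted p-values come from limma. The standard errors at 12 h and 48 h share a spread pooled over both times.

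At 48 h, the 10 largest falls under GSI among the named genes included NOTCH3 and DTX1 of the NOTCH pathway. NOTCH3, a NOTCH receptor, fell 6.17-fold (log2 -2.62 ± 0.125 SE, n = 4, limma adjusted p = 0.000581), and DTX1, a ubiquitin ligase of the same pathway, fell 11.1-fold (log2 -3.47 ± 0.22, adjusted p = 0.00181). GIMAP5, a GTPase involved in lymphocyte survival, fell 5.52-fold (log2 -2.46 ± 0.15, adjusted p = 0.00181). CR2, a complement receptor, fell by 3.54 ± 0.82 on the log2 scale, CFAP73 by 3.01 ± 0.50, the inhibitory receptor gene CD300A by 2.54 ± 0.53, DPP6 by 2.46 ± 0.46 and the palmitoyltransferase gene ZDHHC22 by 2.45 ± 0.36, with adjusted p from 0.0181 to 0.0451. DNASE1L3, which encodes a DNase, was well above background on 3 of 4 DMSO arrays and on 0 of 4 GSI arrays. It was at least 5.41-fold lower with GSI (adjusted p = 0.043), although its difference in ALL-SIL was -0.18.

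Of the named genes VPREB1, part of the surrogate light chain of immature B cells, had the largest rise at 48 h, 6.86-fold (log2 2.78 ± 0.53, adjusted p = 0.0299). RASGRP1, a Ras activator downstream of antigen receptors, rose 4.32-fold (log2 2.11 ± 0.41, adjusted p = 0.0311). SMPD1, the lysosomal acid sphingomyelinase, rose 4.18-fold (log2 2.06 ± 0.25, adjusted p = 0.0118) and CCR9, a chemokine receptor of thymocytes, 3.65-fold (log2 1.87 ± 0.22, adjusted p = 0.0118). The phosphoinositide genes PIK3R5 and INPP4B rose by log2 values of 1.67 ± 0.25 and 1.62 ± 0.35. CD52, a lymphocyte surface protein, rose by 1.51 ± 0.22, the sodium channel gene SCN3A by 1.86 ± 0.34 and RBM38, an RNA-binding protein, by 1.93 ± 0.44, while TC2N rose 4-fold. Their adjusted p-values lay between 0.0167 and 0.043.

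In all, 1973 of 31009 genes and unnamed transcripts passed limma's threshold at 48 h, 456 higher and 1517 lower with GSI, and 8874 had an unadjusted p under 0.05. Of the 1973, 1968 moved one way in all 4 lines, 413 by over 2-fold (66 up and 347 down), and 1029 have a symbol. The median of all genes at 48 h was -0.105, and the split into rises and falls moved with the scaling. It was 1016 and 287 with array medians (all-gene median 0.093), 571 and 703 with quantiles, 1359 and 1384 with normexp and quantiles, and 647 and 534 in the authors' table. Without HPB-ALL the count was 10, without DND-41 14, without TALL-1 2 and without ALL-SIL 812. It was 0 without the replicate block, 0 with only the 8 arrays of that time, 482 with the cell line as a block over both times, and 378 with no filter on dim probes. Slide 1, the only slide with more than 1 line, gave 0 on its own with 5675 at an unadjusted p under 0.05. Of the 1973 calls 100%, 100% and 99.9% had the same direction within slides 1, 2 and 3. The calls were selected on these same lines, so that agreement was set by the selection and is no separate evidence.

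The NOTCH1 target list, genes chosen as direct or pathway targets, addresses whether GSI lowered NOTCH signalling output. Of its 27 measured members, 10 fell and 0 rose at 48 h, and 14 fell and 0 rose when adjusted over the list alone. Besides NOTCH3, DTX1 and CR2, falls were found for the transcriptional repressors HES4 (log2 -2.41 ± 0.42, adjusted p = 0.0258) and HEY1 (-2.43 ± 0.56, adjusted p = 0.0441) and for MYC, a growth regulator (-1.84 ± 0.32, adjusted p = 0.0262). LZTFL1, TASP1, SHQ1 and NOTCH1 itself fell by 1.12 ± 0.17, 1.23 ± 0.25, 0.67 ± 0.16 and 0.67 ± 0.12. Classical targets with a wide spread between lines did not pass, with NRARP at -2.80 (from -7.75 in TALL-1 to -0.23 in DND-41, well above background on 2 of 4 arrays in each group, adjusted p = 0.142), HES5 at -1.79 ± 0.61 (0.105), HES1 at -1.55 ± 0.55 (0.115), IL7R at -1.07 ± 0.33 (0.0819) and PTCRA at -0.36 ± 0.67 (0.758). The median of the list was -0.675, with -1.07 in HPB-ALL, -0.61 in DND-41, -0.92 in TALL-1 and -0.55 in ALL-SIL. The list fell relative to other genes (camera adjusted p = 1.11e-05), with adjusted p = 0.143 with an estimated correlation. fry, which sets a list against no change and not against other genes, gave an adjusted p of 0.000692.

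**Figure D1:**
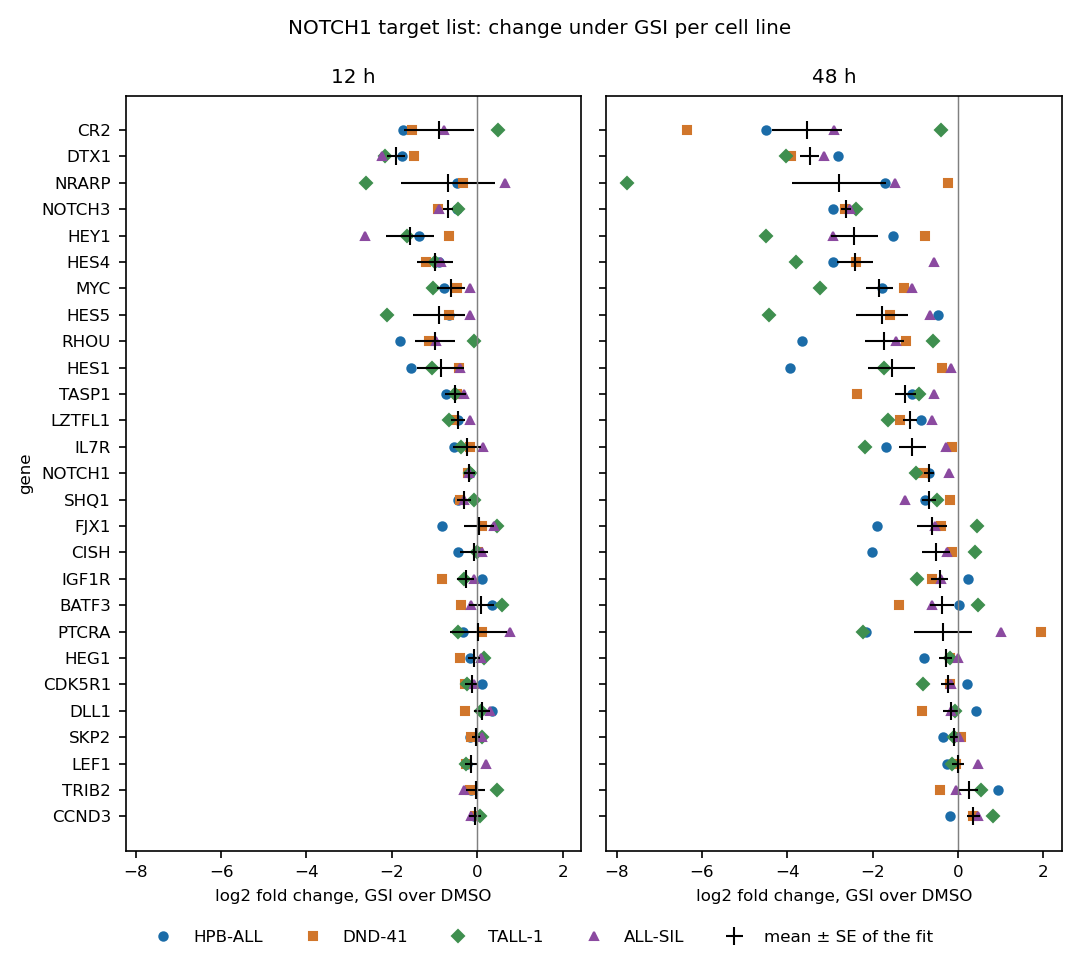
Log2 fold change of GSI over DMSO (x axis) for the 27 measured NOTCH1 target genes (y axis) at 12 h and 48 h. Coloured points are the 4 cell lines, and black bars are the mean ± SE of the limma fit; NOTCH3 points at 48 h lie between -2.94 and -2.38, while those of PTCRA fall on both sides of 0.

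Genes of ribosome production were lower with GSI at 48 h. Among 32 members of the ribosome biogenesis and MYC target list, 19 fell and 0 rose, and 27 fell and 0 rose adjusted over the list alone, with a median of -0.549. The nucleolar genes RRS1 (-1.03 ± 0.14), WDR43 (-0.87 ± 0.11), GNL3 (-0.83 ± 0.13) and NOLC1 (-0.69 ± 0.09) led, with adjusted p from 0.0135 to 0.02. camera gave an adjusted p of 5.43e-13, with adjusted p = 0.21 with an estimated correlation and 0.00227 by fry. Host genes of small nucleolar RNAs, which guide ribosomal RNA modification, were lower as well. Of 17 such lncRNAs 8 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.452 and falls of 1.53 ± 0.23 for SNHG4, 0.71 ± 0.11 for SNHG17, 0.51 ± 0.09 for GAS5 and 0.50 ± 0.09 for ZFAS1. Their camera adjusted p was 3.21e-06, with adjusted p = 0.252 with an estimated correlation and 0.00357 by fry.

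Of 22 quiescence and FOXO target genes, 5 rose and 0 fell at 48 h (6 and 0 adjusted over the list alone), among them BTG2, an antiproliferative gene (1.09 ± 0.08, adjusted p = 0.00242), the inhibitors of cyclin-dependent kinases CDKN2D (0.93 ± 0.11) and CDKN1B (0.53 ± 0.10), and CCNG2 (0.91 ± 0.12). The median was 0.442 and the camera adjusted p 7.03e-08, with adjusted p = 0.143 with an estimated correlation and 0.00227 by fry. The median ran from 0.213 to 0.64 over 5 other scalings and from 0.247 to 0.479 with a line left out, and camera's preset call held in each. Mitosis genes lay higher too, with 2 of 24 rising and 0 falling (3 and 0 adjusted over the list alone), a median of 0.157 and a camera adjusted p of 3.65e-07, with adjusted p = 0.252 with an estimated correlation and 0.0385 by fry. The 2 were KIF20A (0.48 ± 0.09), a spindle motor, and TOP2A (0.51 ± 0.12), a topoisomerase. In the DNA replication list 1 of 30 genes fell, CDK6 (-0.55 ± 0.11, adjusted p = 0.0338), and 1 adjusted over the list alone; 0 rose, and the list had a median of -0.043 and a camera adjusted p of 0.995.

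Survival and T-cell genes went both ways at 48 h. In the T cell and thymocyte list 4 of 32 genes fell and 2 rose (4 and 3 adjusted over the list alone). The surface markers CD7 (-1.35 ± 0.21), CD1B (-1.11 ± 0.18) and CD3D (-0.70 ± 0.13) fell. The list median was 0.277 (camera adjusted p = 0.0249, upward), with adjusted p = 0.144 with an estimated correlation and 0.179 by fry. That camera call ended without HPB-ALL (0.0506) or TALL-1 (0.064), and with array medians (0.218), quantiles (0.0745) or the authors' table (0.12). It also ended with the filter on all 16 arrays (0.313), each probe alone (0.0915) or spike-in scaling, which left out TALL-1 as well (0.118). Of 18 BCL2 family genes, the survival genes MCL1 (0.58 ± 0.11) and BCL2L1 (0.62 ± 0.12) rose and the death ligand TNFSF10 fell (-0.64 ± 0.13), with 4 rising and 2 falling adjusted over the list alone and a list adjusted p of 0.0983 at a median of 0.034 (0.0316 with normexp and the 75th percentile, 0.0331 with no filter on dim probes). Of 18 p53 targets, TP53INP1 (1.43 ± 0.23) and ZMAT3 (0.51 ± 0.08) rose and TNFRSF10B (-0.73 ± 0.17) and AEN (-0.59 ± 0.14) fell, with 5 rising and 2 falling adjusted over the list alone. The p53 list had a median of 0.029 and an adjusted p of 0.0211, with adjusted p = 0.144 with an estimated correlation and 0.0341 by fry. The camera call ended without TALL-1 (0.0581), with quantiles (0.0712), with normexp and quantiles (0.0597) and with spike-in scaling, which left out TALL-1 as well (0.118).

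Metabolic lists depended on single lines at 48 h. For cholesterol synthesis 0 of 21 genes passed (0 adjusted over the list alone), with medians of -0.62 in HPB-ALL, 0.44 in DND-41, 0.01 in TALL-1 and 0.91 in ALL-SIL. The list median was 0.215 (camera adjusted p = 0.00409), with adjusted p = 0.615 with an estimated correlation and 0.522 by fry, and the camera value was 0.0634 without DND-41, 0.59 without ALL-SIL and 0.05 with array medians, which ended the call. In the ATF4 and amino acid list 1 of 21 genes fell, ATF4 itself (-0.40 ± 0.09), against 5 adjusted over the list alone. Its median of -0.306 had a camera adjusted p of 0.016, with adjusted p = 0.553 with an estimated correlation and 0.1 by fry, and 0.365 without HPB-ALL. Of 19 glycolysis genes PFKM, a phosphofructokinase, fell (-0.62 ± 0.13), against 3 adjusted over the list alone, and the median was -0.237 (adjusted p = 0.0651, or 0.014 without DND-41, 0.0364 without TALL-1 and 0.042 with the filter on all 16 arrays). Among 20 heat shock and unfolded protein genes the mitochondrial chaperones HSPE1 (-0.61 ± 0.10) and HSPD1 (-0.55 ± 0.11) fell and EDEM1 rose (0.49 ± 0.11), with the same numbers, 1 rising and 2 falling, adjusted over the list alone. The heat shock median was 0.127 (camera adjusted p = 0.0446), with adjusted p = 0.553 with an estimated correlation and 0.522 by fry, and the camera value was 0.0634, 0.0719 and 0.123 without DND-41, TALL-1 and ALL-SIL. That call also ended with the filter on all 16 arrays (0.162), each probe alone (0.0549), array medians (0.05) and spike-in scaling, which left out TALL-1 as well (0.118).

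Markers of other cell types showed no list-wide shift past the threshold at 48 h. In the B cell list VPREB1 rose and CD24, well above background on 2 of 4 arrays in each group, fell (-1.34 ± 0.31), also adjusted over the list alone, with a median of -0.247 over 12 genes and a camera adjusted p of 0.995. CTSG, a granule protease, fell (-1.09 ± 0.25) among 8 myeloid genes (2 fell adjusted over the list alone), whose median was -0.189 and adjusted p 0.995. Erythroid (10 genes, median -0.059, adjusted p = 0.995) and stromal or epithelial genes (8 genes, median -0.152, adjusted p = 0.457) had 0 members past the threshold, over all genes or adjusted over the list alone. Among 21 interferon response genes IRF7 rose (0.41 ± 0.10), against 2 rising and 1 falling adjusted over the list alone. The interferon median was -0.126, while the mean was 0.001, camera pointed up (adjusted p = 0.37) and fry down (0.834).

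**Figure D2:**
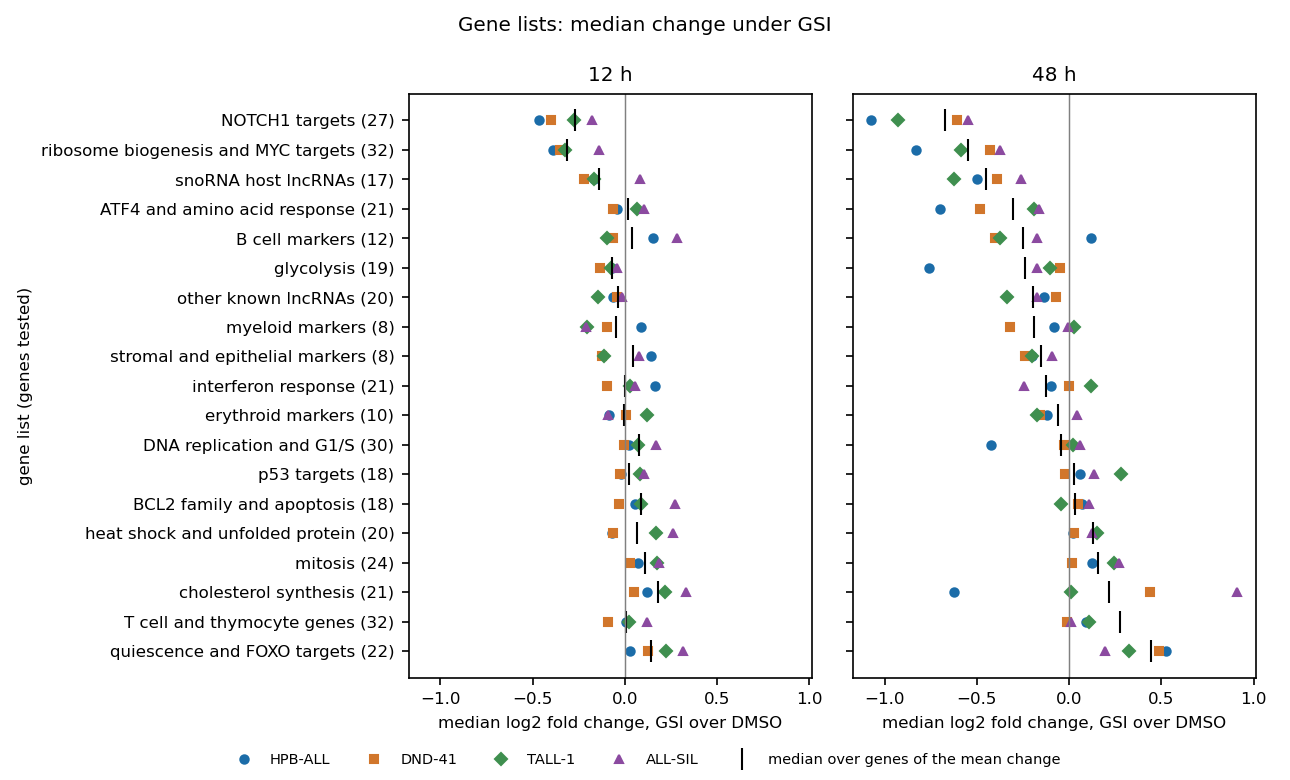
Median log2 fold change of GSI over DMSO (x axis) for the 19 gene lists (y axis, genes tested in brackets) at 12 h and 48 h. Coloured points are medians within each of the 4 cell lines, and black marks are medians of the mean change; the cholesterol points at 48 h run from -0.62 to 0.91.

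At 12 h DTX1 and GIMAP5 came nearest among genes with a symbol, and no gene passed the threshold. DTX1 stood at -1.91 ± 0.22 and GIMAP5 at -1.38 ± 0.15 (limma adjusted p = 0.229 for both), with each of the 4 lines below 0. Next came PCBP3, an RNA-binding protein gene (1.99-fold lower, adjusted p = 0.387), P2RX5, an ATP receptor (-0.59 ± 0.09, 0.637), and MDN1, a ribosome assembly factor (-0.60 ± 0.10, 0.637). On the upper side stood BTG2 (0.53 ± 0.08, adjusted p = 0.469), VANGL2 (0.59 ± 0.09), SOX3 (0.73 ± 0.14), ELOVL4 (0.54 ± 0.10) and LHX9 (0.78 ± 0.16), the last 4 with adjusted p from 0.637 to 0.771. SOX3 and LHX9 were well above background on 1 and 2 of 4 DMSO arrays, so their sizes are uncertain. limma called 0 of 31009 genes at 12 h, with 1626 at an unadjusted p under 0.05 against 1550 by chance, and 1 with normexp and the 75th percentile, 1 with the filter on all arrays, 5 with an intensity trend and 0 without the replicate block. Scaling to spike-ins without TALL-1 called 53.

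Gene lists showed shifts at 12 h in the same NOTCH and ribosome groups. NOTCH1 targets had a median of -0.273, with 0 of 27 past the threshold, 2 falling adjusted over the list alone, and HEY1 at -1.57 ± 0.56, HES4 at -0.99 ± 0.42, NOTCH3 at -0.68 ± 0.125 and MYC at -0.62 ± 0.32. The camera adjusted p was 1.07e-06, with adjusted p = 0.166 with an estimated correlation and 0.0911 by fry. Ribosome biogenesis genes had a median of -0.312, and 31 of 32 were lower with GSI, 0 past the threshold and 11 falling adjusted over the list alone. NOP16 stood at -0.53 ± 0.15 and POLR1B at -0.49 ± 0.12, and the camera adjusted p was 7.56e-20, with adjusted p = 0.244 with an estimated correlation and 0.0911 by fry. Within slides 1, 2 and 3 the medians of NOTCH1 targets were -0.353, -0.274 and -0.179, and those of ribosome genes -0.375, -0.326 and -0.139. camera also called quiescence genes (median 0.14, adjusted p = 0.00162, and adjusted p = 0.352 with an estimated correlation; 1 rising adjusted over the list alone), mitosis genes (0.109, 2.35e-05, and adjusted p = 0.596 with an estimated correlation) and snoRNA hosts (-0.142, 0.00145, and adjusted p = 0.661 with an estimated correlation). With normexp and the 75th percentile the quiescence and mitosis calls ended (adjusted p = 0.101 and 0.0978). All 24 mitosis genes were higher, with 0 of them or of the snoRNA hosts past the threshold adjusted over the list alone.

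Cholesterol genes (median 0.178, camera adjusted p = 0.0039) and DNA replication genes (0.077, 0.00752) were called at 12 h as well, each with adjusted p = 0.717 with an estimated correlation and 0 genes past the threshold adjusted over the list alone. Their named members were INSIG1 (0.35 ± 0.27), MVK (0.31 ± 0.18), CCNE2 (0.36 ± 0.15) and TK1 (0.19 ± 0.09). Without TALL-1 the cholesterol value was 0.0523 and the DNA replication value 0.0634, and without ALL-SIL the DNA replication value was 0.303. With normexp and the 75th percentile both calls ended (adjusted p = 0.396 for cholesterol and 0.997 for DNA replication). The DNA replication median was -0.01 in the authors' table (adjusted p = 0.145). Spike-in scaling without TALL-1 moved all genes at 12 h to a median of -0.096, and the medians of DNA replication, mitosis and quiescence genes to -0.046, -0.007 and -0.019, all still above it. It ended these calls (camera adjusted p = 0.388, 0.276 and 0.231) and that of snoRNA hosts (0.276). Leaving out TALL-1 alone had already ended the DNA replication call. Calls were gained at 12 h for heat shock genes without HPB-ALL (0.0162), without DND-41 (0.00526) or with normexp and quantiles (0.0441), for BCL2 family genes without DND-41 (0.0393) or with the filter on all 16 arrays (0.0205), and for glycolysis with normexp and the 75th percentile (0.00106). In all, 7 of 19 lists passed at 12 h and 10 at 48 h with the preset correlation, 0 and 0 with the estimated one, and 0 and 6 by fry.

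lncRNAs with symbols changed in both directions at 48 h. LINC01120 fell 6.35-fold (log2 -2.67 ± 0.26, limma adjusted p = 0.00896), LINC00977 by 1.74 ± 0.27, LINC00928 by 1.70 ± 0.22, SNHG4 by 1.53 ± 0.23 and PVT1, the neighbour of MYC, by 1.26 ± 0.20. TCF12-DT rose by 1.13 ± 0.27 (adjusted p = 0.0493), LINC00324 by 1.07 ± 0.18, SCOC-AS1 by 0.87 ± 0.20, HCG27 by 0.58 ± 0.12 and LOC100128288 by 0.58 ± 0.09. Among 20 other known lncRNAs fixed as a list, PVT1 and CYTOR (-0.72 ± 0.15) fell and 0 rose, with 4 falling adjusted over the list alone, a median of -0.197 and an adjusted p of 0.35 (0.0495 without DND-41). Of the unnamed custom transcripts, TCONS_00011496 rose 6.64-fold (log2 2.73 ± 0.54) and TCONS_00005924 6.51-fold (2.70 ± 0.53), while TCONS_00016514 fell 7.93-fold (-2.99 ± 0.29) and TCONS_00022343, on 0 of 4 GSI arrays well above background, was at least 2.28-fold lower. TCONS_00005924 was well above background on 2 of 4 DMSO arrays and TCONS_00016514 on 2 of 4 GSI arrays, so their sizes are uncertain. At 12 h LINC01120 stood at -1.34 ± 0.26 (adjusted p = 0.771), FLJ12825 at -1.01 ± 0.22, LINC00642 at -0.84 ± 0.26, KCNQ1DN at -0.75 ± 0.25 and SNHG20 at -0.37 ± 0.10. On the upper side were NOP14-AS1 (0.62 ± 0.14), LINC00487 (0.69 ± 0.21), LINC03019 (0.51 ± 0.16), DRAIC (0.41 ± 0.14) and LINC00996 (0.78 ± 0.26), and 0 lncRNAs passed the threshold at 12 h. FLJ12825, LINC00642, KCNQ1DN, NOP14-AS1, DRAIC and LINC00996 were well above background on only 1 or 2 of 4 arrays of the dimmer group, so their 12 h sizes are uncertain.

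**Figure D3:**
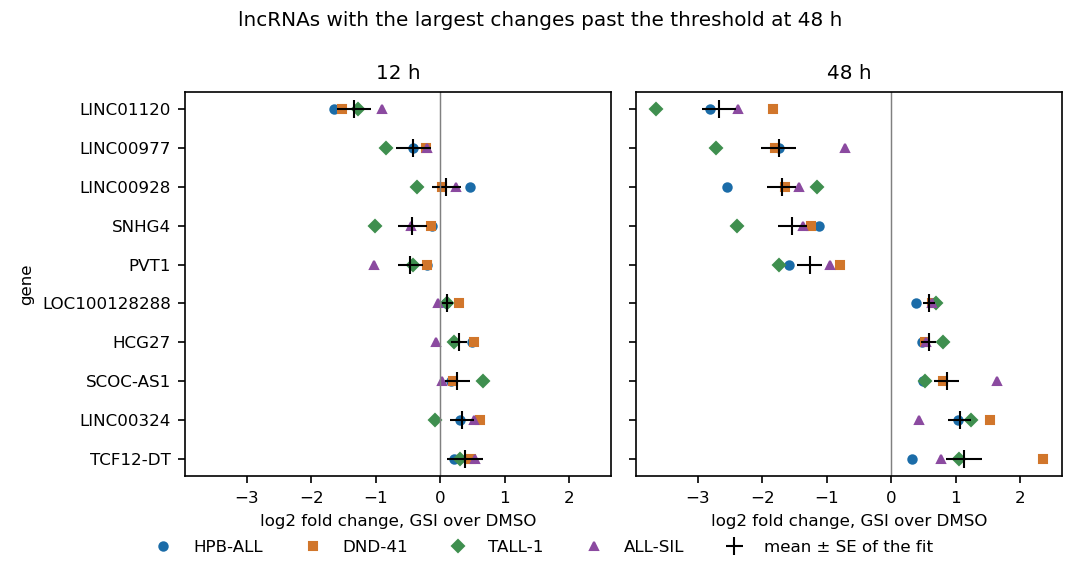
Log2 fold change of GSI over DMSO (x axis) for the 10 named lncRNAs past the threshold at 48 h (y axis), at 12 h and 48 h. Coloured points are the 4 cell lines and black bars the mean ± SE of the limma fit; all 4 points of LINC01120 lie below 0 at both times, between -1.64 and -0.90 at 12 h.

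Custom lncRNA probes passed the threshold at 48 h less often than protein-coding genes, 561 of 9910 (5.66%) against 947 of 14585 (6.49%; odds ratio 0.864, 95% interval 0.775 to 0.964, Fisher's exact test, adjusted p = 0.02, raw p = 0.00795). Custom probes were dimmer, with a median level of -3.95 against 0.74 on the scaled log2 scale, and within 4 classes of similar level the custom probes were not below coding genes by the same test. The odds ratios from dimmest to brightest class were 1.471 (adjusted p = 0.02), 0.996 (1), 1.008 (1) and 1.518 (0.02). The filter on all 16 arrays turned the direction and ended the call (odds ratio 1.075, Fisher's exact test, raw p = 0.121), and spike-in scaling without TALL-1 reversed it (1.835, raw p = 1.88e-08). The odds ratio lay further below 1 with normexp (0.399 with the 75th percentile and 0.443 with quantiles) and in the authors' table (0.576). It was also lower with a trend (0.598), quantiles (0.615), no filter on dim probes (0.727) and array medians (0.791). With each probe alone it was 0.874, and with the mean of a gene's probes 0.893. By Fisher's exact test, the pooled odds ratio was 0.981 without HPB-ALL (raw p = 1), 0.631 without DND-41 (0.749) and 0 without TALL-1 (0.518), but with 10, 14 and 2 genes called there these tests could hardly pass and do not bear on the difference. Without ALL-SIL, where 812 genes were called, the odds ratio was 0.843, in the direction of the main result. RefSeq lncRNAs passed in 49 of 624 cases (7.85%), 13 rising and 36 falling, which was not past the threshold against coding genes by Fisher's exact test (odds ratio 1.227, 95% interval 0.891 to 1.658, adjusted p = 0.31, raw p = 0.186). With array medians the odds ratio was 1.451 (Fisher's exact test, raw p = 0.0277). Other settings turned the direction without passing, with 0.772 in the authors' table and 0.81 with normexp and quantiles (raw p = 0.286 and 0.141). In the brightest class 14 of 84 RefSeq lncRNAs passed, 2 rising and 12 falling, against 473 of 6205 coding genes (odds ratio 2.423, Fisher's exact test, adjusted p = 0.02). Fisher's exact test takes genes as independent, but genes measured in the same 4 lines can move together. Its p-values and intervals for both lncRNA classes can therefore be too small and too narrow. At 12 h 0 genes of any class passed.

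Averaged over both times, DTX1 (-2.69 ± 0.14), NOTCH3 (-1.65 ± 0.09) and ACY3, an aminoacylase (-1.32 ± 0.08), came closest to the threshold among genes with a symbol, each with a limma adjusted p of 0.0558 and below 0 in all 4 lines. GIMAP5 followed at -1.92 ± 0.13 (0.063) and the growth factor gene BMP4 at -1.26 ± 0.10 (0.0773). On the upper side were BTG2 (0.81 ± 0.07, adjusted p = 0.0959), the fatty acid elongase gene ELOVL4 (0.90 ± 0.09, 0.102), the chemokine receptor gene CCR7 (0.75 ± 0.08), GPR174 (0.62 ± 0.07) and HEMGN (0.81 ± 0.10), the last 3 at 0.113. limma called 0 genes with 1 value per line, and 5171 had an unadjusted p under 0.05. Counting the 8 pairs as separate replicates called 631, the filter on all 16 arrays 521, normexp with the 75th percentile 362 and with quantiles 81, the authors' values 1 and array medians 5.

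Whether the GSI effect grew with time was tested on the 48 h minus 12 h difference. Among genes with a symbol, its smallest p-values belonged to ZDHHC22 (-2.85 ± 0.21), SIRPA, an inhibitory receptor (-2.32 ± 0.19), NOTCH3 (-1.94 ± 0.18), VAC14-AS1 (-1.70 ± 0.23) and SNHG4 (2.14-fold lower) on the lower side. TC2N (2.16 ± 0.21), SMPD1 (1.47 ± 0.23), SLC14A1, a urea transporter (1.35 ± 0.19), the adaptor gene DOK2 (1.31 ± 0.16) and LAX1 (0.85 ± 0.12) stood on the upper side. Each had a limma adjusted p of 0.312, and 0 genes passed, with 4217 at an unadjusted p under 0.05. Spike-in scaling without TALL-1 called 125 (all-gene median 0.127), normexp with the 75th percentile 1, and the interaction term in the 16-array fit 0. Of the genes past the threshold at 48 h, 1417 (71.8%) had the same direction at 12 h, where the median was 0.166 for those that rose and -0.091 for those that fell. Across genes, which are not independent replicates, the mean effects at 12 h and 48 h correlated at r = 0.255 (Spearman 0.239).

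In DMSO cultures, HES7, a NOTCH-regulated repressor, was not well above background on any 12 h array and was at least 2.43-fold higher at 48 h (limma adjusted p = 0.507). The angiogenic factor gene VEGFA stood at 1.57 ± 0.22, KLHL34 at 1.92 ± 0.28 and RNF215 at 1.03 ± 0.15. Lower at 48 h were CFAP52 (-1.14 ± 0.17), the metallothionein gene MT1G (-1.03 ± 0.20), ADI1 (-0.74 ± 0.15) and CUL2, a ubiquitin ligase scaffold (-0.69 ± 0.14), while OR13H1 was at least 1.04-fold lower. Their adjusted p-values lay between 0.507 and 0.535. limma called 0 genes in this background comparison, with 2411 at an unadjusted p under 0.05, and 0 without the replicate block. normexp with the 75th percentile called 19 (all-gene median 0.151) and spike-in scaling without TALL-1 called 207 (all-gene median -0.317).

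Between cell lines, the GSI effect over both times differed most by p-value for PDGFRB, a growth factor receptor, at 0.74 in HPB-ALL, -1.16 in DND-41, -2.63 in TALL-1 and -0.58 in ALL-SIL. CACNA1D, a calcium channel gene, ran from -1.81 in HPB-ALL to 1.07 in DND-41, and GADD45G, a stress gene, from -3.70 in DND-41 to -0.83 in ALL-SIL. C1orf87, CXCR6, TRABD2B, OR2T12, CPA5, F2R and SOWAHC completed the 10 smallest p-values, all with an adjusted p of 0.727 in limma's moderated F test. That test called 0 genes, with 1924 at an unadjusted p under 0.05, and in simulated data it recovered 0% of changes of any planted size. Scaling to spike-ins without TALL-1 called 213. Effects of different lines correlated across genes at r between 0.173 and 0.305 at 48 h and between -0.01 and 0.131 at 12 h. Within a line, the effects at 12 h and 48 h correlated at 0.225 in HPB-ALL, 0.08 in DND-41, 0.294 in TALL-1 and 0.021 in ALL-SIL.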

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

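The tests of groupings and of dim probes were fixed before the data were examined, while those of spike-ins and slide position were chosen after seeing results. Of the 35 ways to regroup the 8 arrays of a time, 32 could be fitted, and the other 3 part no pair. For 48 h genes 1 way gave as many, the real one (1973, highest other 3), and among the 8 ways that part all 4 pairs the highest other was 0. Every way but the real one leaves GSI effects in the residual, and those that part fewer pairs also use fewer lines, so they could hardly match. The real way is also 1 of only 8 that part all 4 pairs, too few to exclude chance for the genes. For 48 h lists 3 ways did as well (real 10, highest other 11, or 8 when all pairs are parted), and for 12 h lists also 3 (real 7, highest other 7, or 6), so chance is not excluded for either number of lists. For 12 h genes the real count was 0, so all 32 ways did as well (highest other 1) and nothing follows from it. The averaged effect, the difference between times and the change in DMSO cultures also had a real count of 0 (highest other 0), so 8, 8 and 8 of the 8 turnings of the cell lines did as well, again without information.

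At 48 h 1517 genes fell and 456 rose, a balance that depends on scaling. A loss among dim probes stays open, since the median change of the dimmest class minus that of the brightest was -0.004 in HPB-ALL but -0.201 in DND-41, -0.195 in TALL-1 and -0.232 in ALL-SIL, and 1 line against 3 does not exclude it, although the test had been set to need all 4. From dim to bright, falls numbered 300, 323, 327 and 567 and rises 35, 80, 219 and 122. Lower total RNA signal in treated cells would raise spike-ins with GSI, and the lines went both ways (0.419 in HPB-ALL, -0.446 in DND-41, -0.282 in ALL-SIL), so this stays open too. The scaling itself could still set the balance, since array medians gave 1016 rises and 287 falls.

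Each group sat at 1 slide position, so position and group cannot be separated. A drift growing evenly along the slide would have shown at 12 h, where the 2 groups also lie 2 positions apart, but 5.2% of genes had an unadjusted p under 0.05 there against 28.6% at 48 h. An effect of the last position alone remains open, because the GSI 48 h arrays hold 1 position. Arrays with groups placed at random would settle it.

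Spike-in probes of TALL-1 in DMSO at 48 h averaged -2.441, against 4.398 to 5.282 on other arrays. The 7 probes well above background on all other arrays dropped by at least 4.394 log2, although the bound of 2 used for this test was set after the value was seen. The 6 probes averaged were still well above background on this array. Far less spike-in RNA in that sample is a likely cause, but its complete absence is not shown. No such loss was seen in the share of its probes well above background, 56.9% against 42.2% to 60.2% on other arrays. TALL-1 changes at 48 h correlated at 0.271 with other lines, against 0.21 among those lines. That correlation also depends on how large the changes in TALL-1 were, so it cannot exclude a poor array. The array's 75th percentile, 396.1, was the lowest, close to 400.8 for DND-41 in DMSO at 48 h.

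A test for 1 deviating line marks about 1 in 20 groups by chance, and it marked 23 of 269 gene results and 0 of 38 list results. Of the 23, 1 is not reported here. At 12 h the others were LEF1 at 0.2, CALR at 0.45, HSPD1 at 0.07, SNHG15 at -0.02, CD68 at 1.27 and KLF1 at -1.64 in ALL-SIL, DDIT4 at 0.45 and CD28 at -2.52 in TALL-1, BMF at 1.56 in DND-41 and TP53INP1 at 0.03 in HPB-ALL. At 48 h they were TOP2A at 0.89, TTK at 1.06, CDC20 at 0.92, ZFAS1 at -0.58 and CDH1 at -2.62 in TALL-1, HSPA1A at 1.39, PAX5 at -5.65 and COL1A1 at -2.24 in DND-41, LDHB at -0.49 in HPB-ALL and OAS3 at -0.69 in ALL-SIL. CDH1, PAX5 and COL1A1 were well above background on at most 2 of 4 arrays in either group, so the sizes given for them are not measured values. DOK2 stood at 0.89 in ALL-SIL for the difference between times, and VEGFA at 0.82 in TALL-1 for DMSO cultures. Between 12 h and 48 h camera called shifts in NOTCH1 targets (-0.637, adjusted p = 0.00078), ribosome genes (-0.281, 0.00107), mitosis (0.043, 0.0106), ATF4 genes (-0.46, 0.00258), quiescence genes (0.272, 0.000229) and snoRNA hosts (-0.351, 0.00078). With an estimated correlation their adjusted p was 0.49 to 0.567. SOX3 stood at 0.73 at 12 h and -0.47 at 48 h, a difference of -1.193 (limma adjusted p = 0.312). It was well above background on 3 of 4 GSI and 1 of 4 DMSO arrays at 12 h, so these sizes are uncertain and no reversal is shown.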

How the results depend on the processing

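All alternatives but spike-in scaling without TALL-1, which was chosen after seeing results, were fixed before the data were examined. Slide and scan day are already removed by the pair terms, so no separate alternative was run for them. At 12 h the count was 1 with normexp and the 75th percentile, 1 with the filter on all 16 arrays, 5 with an intensity trend and 53 with spike-in scaling. At 48 h it was 1303 with array medians, 1274 with quantiles, 1181 in the authors' values, 2743 with normexp and quantiles, 3671 with the filter on all 16 arrays and 3591 with a trend. It was 378 with no filter on dim probes, 482 with the line as block over both times, 0 with no replicate block and 0 with only the 8 arrays of that time. With a line left out it was 2 to 812. Spike-in scaling, which also left out TALL-1, gave 410 at 48 h, against 2 with TALL-1 left out alone. The averaged effect gave 5 with array medians, 362 and 81 with normexp (75th percentile and quantiles), 1 in the authors' values, 521 with the filter on all arrays and 631 with 8 separate pairs. The difference between times gave 1 with normexp and the 75th percentile and 125 with spike-ins, DMSO cultures 19 and 207, and cell lines 213 with spike-ins. Lists at 12 h numbered 4 with normexp and the 75th percentile, 8 with normexp and quantiles, 4 with spike-ins, 0 with the estimated correlation, 0 by fry and 5 to 9 with a line left out. At 48 h they numbered 0, 6 by fry and 8 to 10. NOTCH1 and ribosome medians of -0.273 and -0.312 at 12 h were not past the threshold with the estimated correlation or fry, nor were -0.675 and -0.549 at 48 h with the former. The 12 h median of DNA replication genes was -0.01 in the authors' values. With spike-ins, which moved the median of all genes to -0.096, the 12 h medians were -0.046 for DNA replication, -0.007 for mitosis, -0.019 for quiescence and -0.03 for B cell markers, all above it, and B cell markers passed (camera adjusted p = 0.0183). The odds ratio of custom probes was 1.075 with the filter on all arrays, 1.835 with spike-ins, 1.471, 0.996, 1.008 and 1.518 within levels, and 0 to 0.981 with a line left out. It lay further below 1 than the main 0.864 with normexp (0.399 and 0.443) and the authors' values (0.576). The same held with a trend (0.598), quantiles (0.615), no filter (0.727) and array medians (0.791). For RefSeq lncRNAs the odds ratio was 1.451 with array medians, 2.423 in the brightest class and 0 to 3.342 with a line left out. It was below 1 in the authors' values (0.772), with normexp and quantiles (0.81), with a trend (0.879) and with normexp and the 75th percentile (0.953). The correlation of effects at 12 h and 48 h was 0.384 with the filter on all arrays. The all-gene median was -0.205 at 48 h with no filter on dim probes and -0.105 for DMSO cultures with array medians, and -0.161 for the difference between times with normexp and the 75th percentile. Of 70 named genes past the threshold at 48 h, all that a setting kept had the same direction there. With a line left out that agreement was largely set by the selection, since 1968 of the 1973 calls moved one way in all 4 lines. Settings that alter only the pairing or the arrays fitted leave the mean change as it is, so their agreement is no evidence. Past the threshold stayed 27 with no filter, 30 with spike-ins without TALL-1 and 48 with array medians. With a line left out, 3 stayed past without HPB-ALL, 4 without DND-41, 2 without TALL-1 and 36 without ALL-SIL. The number was 34 with the line as block over both times, 0 with no replicate block and 0 with only the 8 arrays of that time. The cause of these shifts was not tested.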

Other observations

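Gene families were looked at after seeing the results, and 10 of 485 passed with camera at 12 h and 32 at 48 h, but 0 and 0 with an estimated correlation (adjusted p = 0.997 and 0.648 or more). GIMAP genes, GTPases of lymphocytes that lie in 1 cluster, stood out at both times, with medians of -1.06 at 12 h (camera adjusted p = 1.5e-10) and -1.71 at 48 h (9.2e-05). At 48 h GIMAP8 (-2.37 ± 0.55), GIMAP7 (-2.08 ± 0.22), GIMAP1 (-1.55 ± 0.25), GIMAP6 (-1.06 ± 0.17) and GIMAP2 (-0.82 ± 0.16) fell with GIMAP5, while GIMAP4 at -1.71 did not pass (adjusted p = 0.138). Over 6 scalings the family median ran from -1.714 to -1.177. Among chemokine receptors, which guide lymphocyte migration, 3 of 8 CCR genes rose, CCR7 (1.16 ± 0.11), CCR4 (0.59 ± 0.13) and CCR9, while CCR8 (-0.24), CCR6 (-0.22) and CCR10 (-0.15) were lower without passing and CCR2 (0.97) was above 0 in ALL-SIL alone, and the family median was 0.623 (camera adjusted p = 0.0214). It was 0.04 in HPB-ALL, 0.284 in DND-41, 0.294 in TALL-1 and 1.038 in ALL-SIL, and 0.36 to 0.877 over 6 scalings.

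Of 62 genes and pseudogenes with RPL names, most of them ribosomal proteins, 30 fell at 48 h, with a median of -0.373. With quantile normalization the median was -0.06 against 0.007 for all genes. Whether near-identical copies share probe signal was not tested. Mitochondrial ribosome genes stood at -0.265 (MRPL, 8 of 50 fell) and -0.314 (MRPS, 6 of 28 fell) and RNA polymerase genes at -0.292 (POLR, 10 of 33 fell). With array medians these values were -0.067, -0.116 and -0.094, while the median of all genes moved from -0.105 to 0.093. That scaling shifts all genes of an array by the same amount, so the distance from all genes could not change there. With quantile normalization the values were -0.204, -0.215 and -0.207, against 0.007 for all genes.

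Whether lncRNAs change with their nearest protein-coding gene was a question fixed before the data were examined. Over 475 RefSeq lncRNAs the Spearman correlation at 48 h was 0.126 (permutation p = 0.0055 over 10000 shuffles), 0.031 at 12 h, and 0.093 to 0.136 with other scalings. Shared regulation of neighbours may contribute, though 19 of 35 lncRNAs past the threshold had their neighbour's direction, close to an even share. PVT1 with MYC (-1.26 and -1.84), LINC00324 with CTC1 (1.07 and 0.43), BTG2-DT with BTG2 (0.54 and 1.09) and MIF-AS1 with MIF (-0.47 and -0.64) moved alike. NOP14-AS1 and NOP14 (0.77 and -0.72) and SNHG15 and MYO1G (-0.76 and 0.88) moved apart. A time course of nascent RNA after GSI, with each line cultured more than once, could show which neighbour changes first. Timing alone would not separate shared regulation from an effect of 1 transcript on the other.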
